A study of Xenopus tropicalis with 39 samples.

How the data were processed

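The samples were Xenopus tropicalis embryos or explants, in 39 samples of which 33 were RNA libraries and 6 were chromatin immunoprecipitation (ChIP) samples. RNA libraries were made from polyA RNA by Smart-seq2 cDNA synthesis and tagmentation, per the labels' protocols. The series design text calls the 8-cell samples biological triplicates and the explant and ChIP samples biological duplicates. For each of 3 RNA experiments the authors deposited a table of estimated read counts per feature (expected counts that need not be whole) and a table of TPM (transcript abundance scaled to the same total in each library). Per the submitters' processing notes, RSEM 1.2.12 and Bowtie2 2.2.7 were used for the RNA libraries and Bowtie2 2.2.7 for the ChIP libraries; the genome build and the peak caller are not given in the sources used here. The 4 peak lists (Vegt, Otx1, Foxh1 and H3K4me1) were deposited as 1 list each over pooled replicates, per the peak names, with the authors' score, fold enrichment ratio and summit position per peak, so no replicate comparison of peaks was made. The fold enrichment and score were used only to describe, rank or divide peaks within a list. The Foxh1 list was made by the authors from published data of another series, and 1 library of that series was also used for the Vegt and Otx1 lists, per the series design text. The names of all 15925 H3K4me1 peaks contain the letters meso, while the labels call the tissue vegetal mass; the label was followed.

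Each count table held 32234 features, of which 26550 were gene models with identifiers that start with Xetrov9 and 5684 were long non-coding RNA (lncRNA) models. The files pair no identifier with a gene symbol. None of the identifiers (0) was found in the reference table of 28858 genes of assembly UCB_Xtro_10.0, so no gene names are given. For that reason the 12 gene lists that had been fixed by symbol before the data were examined could not be read, the targets of the injected RNAs and morpholinos could not be followed by name, and the rule for named genes was applied without its symbol part. That rule took, per direction, the gene models with the greatest absolute log2 fold change among those with adjusted p under 0.05, an average log2 CPM (counts scaled by library size) of at least 1 and no overlap between the replicate values of both groups; at most 2 identifiers per direction are printed for a comparison. For the addition of otx1 RNA the rule was applied to the fit with a replicate block, since the fit without it called 0 features. It was also applied to the blocked fits of Vegt MO and Otx1 MO, and of those picks only Xetrov90018018m.g is printed. Identifiers outside the rule were chosen after their values were seen. They were the other feature called in Vegt MO, the features that follow the injected amounts and the 8-cell feature with the most TPM. How reads were divided between near-identical gene copies is not known for single features. The preset tests of sequence motifs in peaks and of peaks near responding genes need a genome or annotation of the peaks' build and were not run.

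Counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, TMM scaling, filterByExpr and 1 group-means model per table, so that groups of 2 shared 1 estimate of the spread. Calls had a Benjamini-Hochberg adjusted p under 0.05. The tables were tested separately and levels were not compared between them by a test. The filter left 13503 features in the 8-cell table, 16360 in the animal cap table and 16269 in the vegetal mass table. Dose trends were single contrasts over scores of log2((dose + 50) / 50) for vegt and log2((dose + 25) / 25) for otx1. Estimated counts per library summed to between 9005402 and 17210721 in the 8-cell table, 8289954 and 18201303 in the caps and 10906279 and 16379814 in the masses.

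Groups of a table share replicate numbers. The deviations of same-numbered libraries from their group means, over features with a mean log2 CPM above 1, correlated with r between 0.43 and 0.68 in the 8-cell table, 0.67 and 0.89 in the caps and 0.71 and 0.82 in the masses (across features, which are not independent replicates). All 9, 16 and 8 libraries correlated best with a library of their own number. In the caps and masses the deviations of a group of 2 mirror each other. Numbers 1 and 2 there give the same correlations, so they count once. The first principal component held 54.7% of the variance in the caps and 51.2% in the masses and parted number 1 from number 2 in both. The numbers were therefore taken to pair the libraries. In the caps and masses a single comparison holds 2 pairs, and that reading rests on all groups of the table. The fit without the block had been set before the data were examined and gives the main values; the fit with the replicate number as a block is printed beside them.

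The tests were tried on simulated counts with the real library sizes and replicate effects and with feature means averaged over the groups. In these counts 200 features were changed, drawn only from those above a minimum fitted mean count. Recovery among features with lower counts was thus not measured. For vegetal against animal blastomeres (12590 features tested) the fit without a block recovered 0% of 2-fold, 26% of 4-fold, 56% of 8-fold and 66% of 16-fold changes, and the fit with it 40%, 58%, 84% and 82%. For caps with 500 ng vegt RNA (15810 features) the shares were 6%, 56%, 72% and 90% without the block and 78%, 98%, 96% and 100% with it. For the Double MO masses (15739 features) they were 0%, 34%, 68% and 82% without the block and 64%, 98%, 98% and 100% with it. Unchanged features made up 1.33%, 0% and 0% of the calls without the block and 10.8%, 7.92% and 11.8% with it, in that order, so that the blocked lists held more chance calls than the 5% the adjustment aims at.

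Sets of features were defined after the data were seen, from the calls of one experiment, and tested in another or in libraries not used to define them, with camera (its default preset correlation, and again with an estimated correlation) and fry of limma 3.58.1; 28 set tests were adjusted together for each fit. Overlaps of call lists used Fisher's exact test, one-sided, over features tested in both tables, 13 tests with the block. Shares of feature classes among calls used Fisher's exact test, two-sided, 84 tests adjusted together. Overlap between comparisons with shared uninjected libraries was set against 20 simulations of unchanged groups in which all libraries were redrawn. Peak overlaps of at least 1 bp were set against 1000 circular shifts of 1 list along each chromosome, whose length was taken as the highest coordinate in the lists; 0.001 is the smallest p these shifts can give. Shifts take no account of mappability or of open chromatin. Peaks of the 3 factors were merged into regions where they overlapped. Intervals of shares are 95% Wilson intervals and cover counting error only. Peaks were also compared with at least 0.5 of a peak covered, with bedtools 2.31.1. Bound regions were stitched into clusters at a distance 0.5 times the 25000 bp of one alternative. Medians of fold changes were also taken with features at 0 in all libraries of one group set to 3 counts over that group. Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma on log2(TPM + 1) with a mean TPM of at least 1, the replicate block, each library left out, only the libraries compared, a linear dose, fold thresholds, overlap and score limits for peaks and other stitching distances; those added after the data were seen are named where they are given. No value column was left out.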

Results

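The series measured RNA in 3 experiments on Xenopus tropicalis embryos and the binding of 3 transcription factors to chromatin. Animal and vegetal blastomeres were separated at the 8-cell stage, when the embryo holds only maternal RNA, and were sequenced with whole embryos (n = 3 each). Animal caps, explants of prospective ectoderm, came from uninjected embryos and from embryos injected with 50, 100, 200 or 500 ng of vegt RNA, or with 100 ng of vegt RNA and 25, 50 or 100 ng of otx1 RNA, with the unit as the labels give it (n = 2 each, 8 groups). These amounts are high for a single embryo, so the unit may be misprinted in the labels; ratios between amounts are unaffected. Vegetal masses, explants of prospective endoderm, came from uninjected embryos and from embryos injected with a morpholino against Vegt, against Otx1 or against both, called Double MO (n = 2 each, 4 groups). A morpholino is an antisense oligomer that blocks translation or splicing of its target. Caps and masses were harvested at stage 10.5, at 7 hours after fertilization. Control explants were uninjected, and no library with a control RNA or control morpholino was used here. Vegt is a T-box factor, Otx1 a homeodomain factor and Foxh1 a forkhead factor that works with Smad proteins. Peak lists covered Vegt and Otx1 in whole embryos at stage 8, Foxh1, and the histone mark H3K4me1, which is found at enhancers, in vegetal tissue at stage 10.5. Estimated counts summed to between 8289954 and 18201303 per library.

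The first comparison asked which maternal RNAs differ between the vegetal and animal parts of the 8-cell embryo. Without the replicate block, vegetal blastomeres held more RNA of 60 of 13503 tested features and less of 3. With the block these counts were 129 and 51, so the small number of animal features depended on the fit. The values that follow are from the fit without the block. The 60 vegetal features differed by a median log2 fold change of 3.18, with a range of 1.254 to 7.51, and 52 of them by at least 4-fold. They were abundant, with a median of 168 TPM and at least 10 TPM in the vegetal blastomeres for all 60. The 3 animal features had a median log2 fold change of -1.56. The most vegetal models by the preset rule were Xetrov90026291m.g, at 248 ± 102 TPM in vegetal and 1.37 ± 1.83 TPM in animal blastomeres (SD, n = 3; log2 fold change 7.51, SE 1.07, edgeR adjusted p = 0.014), and Xetrov90012705m.g, at 325 ± 119 and 1.90 ± 0.59 TPM (log2 fold change 7.42, SE 0.54, adjusted p = 0.00038). The animal models were led by Xetrov90015130m.g, at 184 ± 6.55 TPM in animal and 55.4 ± 12.7 TPM in vegetal blastomeres (log2 fold change -1.72, SE 0.22, adjusted p = 0.0059), and Xetrov90009765m.g, at 1347 ± 142 and 446 ± 101 TPM (log2 fold change -1.56, SE 0.25, adjusted p = 0.027).

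None of the 1453 tested lncRNA models was among the 60 vegetal calls (0%, against 10.8% of features not called, with adjusted p = 0.0062 by Fisher's exact test, two-sided). This test did not match features for level, and all 60 calls had at least 10 TPM in vegetal blastomeres. An effect of level was thus not separated from one of feature class. The whole-embryo mean lay between the animal and vegetal means for all 63 called features and for 47.2% of the others. With the replicate number as a block, 129 features were higher and 51 lower in vegetal blastomeres, and the 63 calls were all among these. Vegetal replicate 3 stood apart, with 64.3% of features at 0 and 7.05% of its TPM in Xetrov90016336m.g; without it 66 features were called, and without the 3 libraries of its number the blocked fit called 247 (an alternative chosen after seeing the data). Leaving out animal replicate 1, 2 or 3 gave 32, 38 or 37 calls, and leaving out vegetal replicate 1 or 2 gave 41 or 36.

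The cap experiment asked how prospective ectoderm responds to rising amounts of vegt RNA. Calls grew in number with the amount. At 500 ng, 114 features were higher than in uninjected caps, by a median log2 fold change of 3.57, and 17 were lower, by a median of -2.12; both medians stayed as they are with features at 0 counts in one group set to their bound. At 200 ng, 24 were higher and 1 lower, and at 50 and 100 ng 0 were called, with 174 and 277 features at an unadjusted p under 0.05 (edgeR; DESeq2 called 21 and 43 and limma on TPM 0 and 2). Across all amounts, 165 features rose and 30 fell with the dose score. Features with a mean under 0.1 TPM in the 8-cell libraries were 37 of the 114 that rose at 500 ng (32.5%), against 10.6% of features not called (Fisher's exact test, two-sided, adjusted p = 2.22e-09). They were also 5 of the 17 that fell (29.4%, adjusted p = 0.056). With the replicate block they were 40% of those that rose and 29.1% of those that fell, against 9.67% of features not called (adjusted p = 6.8e-62 and 2.44e-15), so the excess was not limited to features that rose. The lncRNA models made up 35 of the 114 (30.7%), against 14.9% of features not called (adjusted p = 6.08e-05). Neither class was matched for level in these tests, so an effect of level was not separated from one of feature class.

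By the preset rule, Xetrov90012981m.g reached 61.1 ± 8.12 TPM at 500 ng against 0.26 ± 0.36 TPM in uninjected caps (SD, n = 2; edgeR adjusted p = 0.0034), and Xetrov90013793m.g reached 52.1 ± 35.7 against 0.35 ± 0.27 TPM (adjusted p = 0.0023). Xetrov90002368m.g was at 0.17 ± 0.06 TPM against 5.29 ± 4.26 TPM (adjusted p = 0.033), and Xetrov90011815m.g at 0.36 ± 0.08 against 3.38 ± 0.73 TPM (log2 fold change -3.19, SE 0.48, adjusted p = 0.014). Xetrov90002928m.g, singled out after its values were seen, rose with the amount, from 128 ± 49.7 TPM in uninjected caps to 1090 ± 320, 2005 ± 121, 3165 ± 320 and 8640 ± 596 TPM at 50, 100, 200 and 500 ng; it was also vegetal at the 8-cell stage (log2 fold change 3.95, adjusted p = 0.00095). With the replicate block, 7, 63, 197 and 460 features were higher and 0, 8, 22 and 230 lower at 50, 100, 200 and 500 ng. That fit kept all 131 calls of the 500 ng comparison and called 538 features rising and 289 falling with dose. Without the block, the 195 trend calls became 95 or 82 without uninjected replicate 1 or 2, 125 or 74 without replicate 1 or 2 of the 500 ng caps, 106 without 200 ng replicate 1, 127 without 100 ng replicate 2 and 126 without 50 ng replicate 2. At 500 ng without the block, leaving out uninjected replicate 1 or 2 gave 54 or 60 calls, and leaving out replicate 1 or 2 of the 500 ng caps gave 82 or 44. At 200 ng, leaving out uninjected replicate 1 or 2 gave 0 or 17, and leaving out replicate 1 or 2 of the 200 ng caps gave 0 or 2. At 100 ng, leaving out uninjected replicate 2 gave 2.

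**Figure D1:**
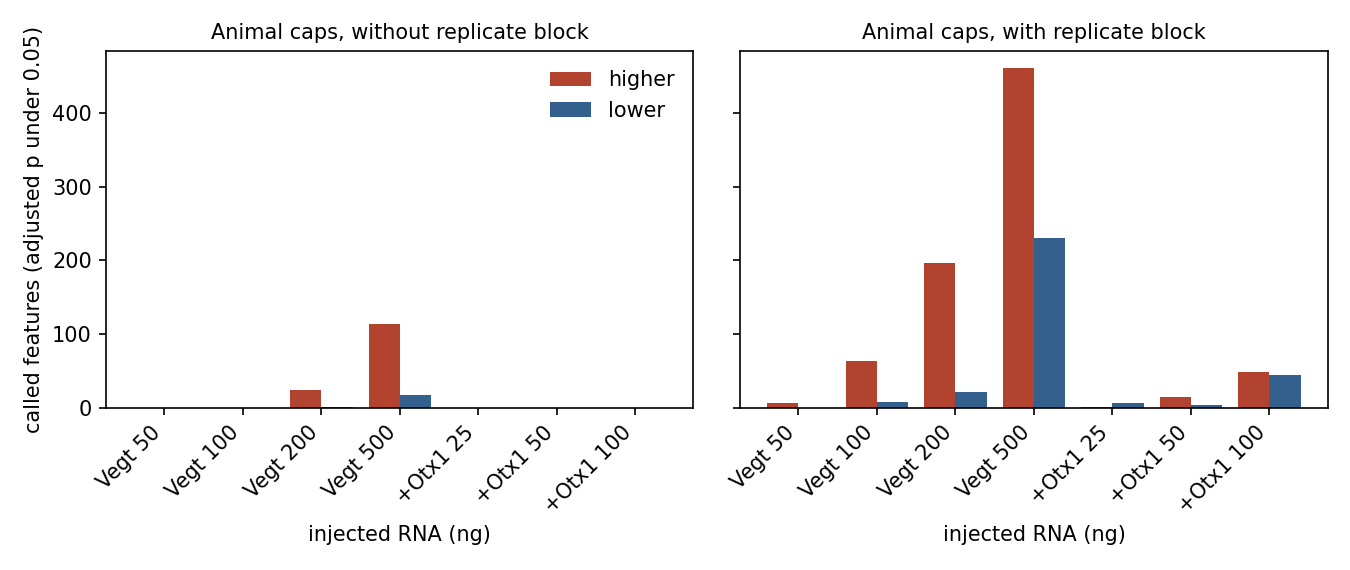
Number of features called higher (red) or lower (blue) in animal caps per amount of injected RNA in ng, in the fits without and with the replicate number as a block; vegt amounts are against uninjected caps and otx1 amounts against 100 ng of vegt RNA alone. Calls at 500 ng of vegt RNA were 114 higher and 17 lower without the block and 460 and 230 with it.

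The next comparison asked what otx1 RNA adds to 100 ng of vegt RNA. Without the block edgeR called 0 features at 25, 50 or 100 ng and 0 in the otx1 dose trend, with 180, 248, 424 and 424 features at an unadjusted p under 0.05; DESeq2 called 1, 15, 40 and 45 and limma on TPM 0, 0, 6 and 8. With the replicate block, 48 features were higher and 44 lower at 100 ng, 15 and 4 at 50 ng and 1 and 6 at 25 ng, and 66 rose and 57 fell in the trend. In that fit Xetrov90002688m.g was at 18.6 ± 5.91 TPM with 100 ng of otx1 RNA and at 0.03 ± 0.04 TPM without it (SD, n = 2; adjusted p = 0.00047 with the block and 0.29 without), and Xetrov90016048m.g at 164 ± 25.7 and 0.85 ± 1.195 TPM (0.0026 and 0.51). Xetrov90000697m.g was at 2.75 ± 1.78 TPM with and 16.8 ± 10.0 TPM without otx1 RNA (0.00093 and 1), and Xetrov90005150m.g at 1.64 ± 0.58 and 8.73 ± 2.199 TPM (0.034 and 0.56). Xetrov90013341m.g, also singled out after its values were seen, followed the otx1 amount, with 45.7 ± 4.22 TPM at 0 ng and 726 ± 244, 1699 ± 736 and 3075 ± 859 TPM at 25, 50 and 100 ng. It was vegetal at the 8-cell stage (log2 fold change 3.45, adjusted p = 0.0017).

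**Figure D2:**
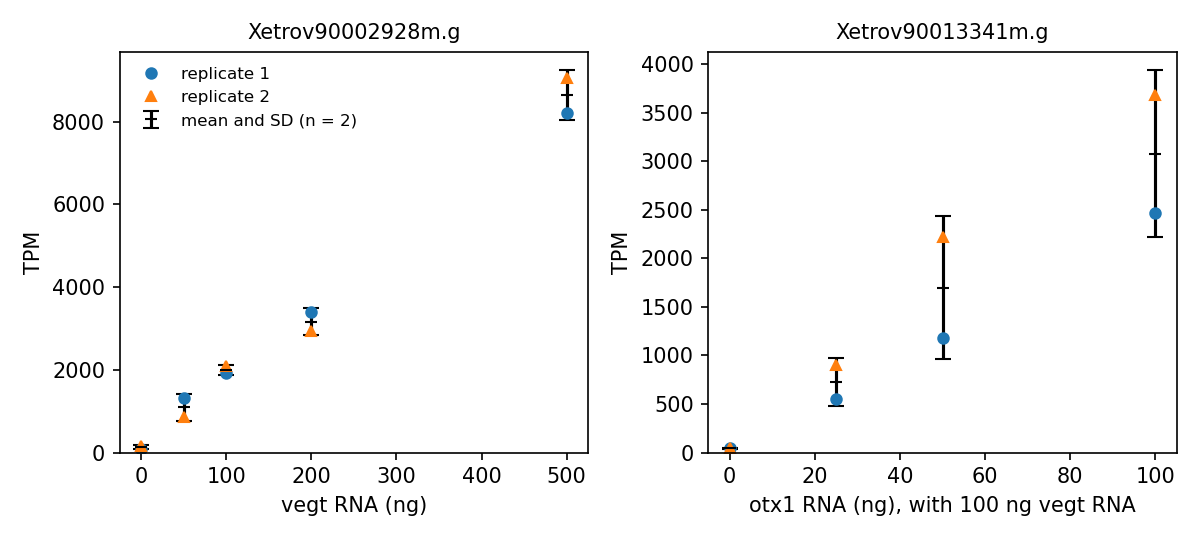
TPM of the feature that followed the vegt amount (left) and of the one that followed the otx1 amount (right) against injected RNA in ng; circles and triangles are replicates 1 and 2, and black marks show mean and SD (n = 2). The left feature reached 8640 TPM at 500 ng and the right one 3075 TPM at 100 ng.

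The set of 114 features that rose with 500 ng of vegt RNA, called the Vegt-induced set, was then followed with otx1 RNA added. Their median log2 fold change at 100 ng of otx1 RNA was 0.04, and 56 of 114 were negative. The camera test of limma against other features gave adjusted p = 0.86, and adjusted p = 0.96 with an estimated correlation. The fry test of limma for changes in either direction gave adjusted p = 1.53e-05. With the block, 4 of them were higher and 6 lower. At 25 ng and in the otx1 trend camera did not call the set (adjusted p = 0.53 and 0.41). There fry for changes in either direction gave adjusted p = 0.065 and 1.14e-05. At 50 ng its median was 0.05, with 50 of 114 negative, and replicates 1 and 2 went opposite ways (medians of -0.085 and 0.27). Camera gave adjusted p = 0.0018 there, and adjusted p = 0.56 with an estimated correlation. The fry test for changes in either direction gave adjusted p = 0.0021. The 17 features that fell with 500 ng of vegt RNA, called the Vegt-lowered set, had medians of -0.01, -0.21 and -0.33 at 25, 50 and 100 ng of otx1 RNA and -0.16 in the trend, with 12 of 17 negative at 50 and 100 ng and in the trend. Camera gave adjusted p = 0.61, 0.034, 0.00082 and 0.00022 in that order, and adjusted p = 0.85, 0.50, 0.31 and 0.31 with an estimated correlation; with the block the 50 ng call was lost (camera adjusted p = 0.071). The 60 vegetal maternal features were not called by camera with 500 ng of vegt RNA (median -0.03, adjusted p = 0.32) or with 100 ng of otx1 RNA added (median 0.04, adjusted p = 0.50). With 500 ng of vegt RNA 3 of them were called higher and 0 lower, and fry for changes in either direction gave adjusted p = 1.97e-05. With otx1 RNA added that fry test gave adjusted p = 0.30 (4.15e-07 with the block). The set includes Xetrov90002928m.g and Xetrov90013341m.g, which followed the injected amounts of vegt and otx1 RNA. It was not tested without them, so these fry values may rest partly on them.

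The morpholino experiment asked how prospective endoderm responds to loss of Vegt, Otx1 or both. The Vegt-induced set of the caps was lower in the morpholino masses: its 111 tested members had a median log2 fold change of -0.59 in Vegt MO, -0.38 in Otx1 MO and -0.71 in Double MO, with 70.3%, 72.1% and 81.1% of members negative. Within replicates 1 and 2 the medians were -0.43 and -0.58 in Vegt MO, -0.19 and -0.31 in Otx1 MO and -0.65 and -0.79 in Double MO. These 3 comparisons use the same 2 uninjected libraries, so their directions are not independent. The camera test gave adjusted p = 1.08e-05, 0.00022 and 2.73e-13 in that order. With an estimated correlation adjusted p = 0.064, 0.090 and 0.022, so that of these 3 the Double MO call remained below the threshold; with the block these became 0.042, 0.084 and 0.033. The fry test for a change in one direction gave adjusted p = 0.095, 0.13 and 0.039 in that order (0.014, 0.036 and 0.014 with the block). The set was also lower in Double MO than in Otx1 MO, by a median of -0.48 with 82 of 111 negative. Camera there gave adjusted p = 7.99e-11, and adjusted p = 0.022 with an estimated correlation (0.033 with the block). The fry test there gave adjusted p = 0.084 (0.014 with the block). Between Double MO and Vegt MO the median was -0.32 (camera adjusted p = 5.97e-05, and adjusted p = 0.090 with an estimated correlation), and the interaction was not called (camera adjusted p = 0.59). The Vegt-lowered set was higher in Vegt MO, where 13 of its features were tested and had a median log2 fold change of 1.47 (1.29 and 1.60 within replicates 1 and 2; 11 of 13 were not negative). Camera gave adjusted p = 8.52e-09, and adjusted p = 0.21 with an estimated correlation (0.042 with the block). The fry test for a change in one direction gave adjusted p = 0.13 (0.014 with the block). The set was not called in the other masses: its median was -0.21 in Otx1 MO, where 8 of 13 were negative (camera adjusted p = 0.56), and 0.44 in Double MO (camera adjusted p = 0.27). Between Double MO and Vegt MO its median difference was -0.54 (camera adjusted p = 5.36e-05, and adjusted p = 0.31 with an estimated correlation). Between Double MO and Otx1 MO it was 0.57 (camera adjusted p = 0.0067, and adjusted p = 0.48 with an estimated correlation), and in the interaction -0.44 (camera adjusted p = 5.84e-05, and adjusted p = 0.31 with an estimated correlation).

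For the 60 vegetal maternal features camera with its preset correlation gave adjusted p = 0.0018 in Vegt MO, 0.092 in Otx1 MO and 0.035 in Double MO (0.080 with the block), and adjusted p = 0.56, 0.72 and 0.72 with an estimated correlation. For Double MO against Vegt MO, Double MO against Otx1 MO and the interaction, the preset values were 6.1e-08, 0.38 and 2.19e-05, with adjusted p = 0.34, 0.85 and 0.46 with an estimated correlation, so no call of this set remained. Their medians were -0.22 in Vegt MO, 0.13 in Otx1 MO and 0.16 in Double MO, and replicates differed: within replicates 1 and 2 the medians were -0.33 and -0.056 in Vegt MO, -0.18 and 0.63 in Otx1 MO and -0.13 and 0.77 in Double MO. Within number 2, the uninjected and Vegt MO masses were thus close to each other in these features and below the Otx1 MO and Double MO masses.

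**Figure D3:**
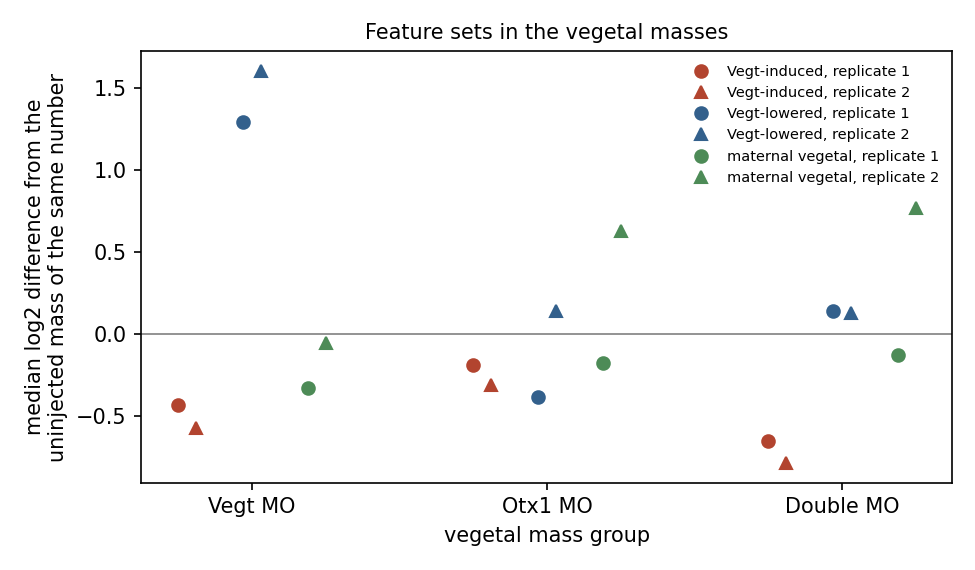
Median log2 difference between each morpholino mass and the uninjected mass of the same replicate number for 3 sets of features; circles are replicate 1 and triangles replicate 2. The Vegt-induced set lies below 0 in both replicates of each group, from -0.19 to -0.79, and the Vegt-lowered set is at 1.29 and 1.60 in Vegt MO. Values of the same replicate number share 1 uninjected library, so they are not independent.

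Single features were called in small numbers without the block. Vegt MO had 2 lower features and 0 higher, Otx1 MO had 0 calls (826 features at an unadjusted p under 0.05; DESeq2 called 59 and limma 0) and Double MO had 1 higher and 9 lower. DESeq2 called 84 higher and 77 lower in Vegt MO, and edgeR without the filter on low counts 28 and 20, so the balance of directions there depended on the setting. Both features lower in Vegt MO were also lower in Double MO. They were Xetrov90018018m.g, at 3.45 ± 0.34 TPM in Vegt MO, 50.5 ± 1.58 TPM in Otx1 MO and 51.2 ± 0.86 TPM in uninjected masses (SD, n = 2; Vegt MO edgeR adjusted p = 0.024), and Xetrov90026354m.g, at 10.3 ± 0.50 TPM in Vegt MO and 90.8 ± 8.66 TPM in Otx1 MO (Vegt MO adjusted p = 0.036). Xetrov90009021m.g rose to 62.4 ± 1.245 TPM in Double MO from 7.87 ± 2.77 TPM in uninjected masses (SD, n = 2; log2 fold change 2.89, SE 0.25, edgeR adjusted p = 0.027). It was at 75.3 ± 0.47 TPM in Otx1 MO (adjusted p = 0.074, and 0.00067 with the block) and at 12.24 ± 2.14 TPM in Vegt MO. In Double MO Xetrov90026354m.g fell to 9.46 ± 0.30 from 122 ± 20.6 TPM (log2 fold change -3.83, SE 0.27, adjusted p = 0.027), and Xetrov90010375m.g to 2.36 ± 0.17 from 17.95 ± 0.82 TPM (log2 fold change -3.05, SE 0.26, adjusted p = 0.027). Xetrov90010375m.g was at 2.27 ± 0.27 TPM in Otx1 MO (adjusted p = 0.074, and 0.00085 with the block) and at 10.7 ± 0.26 TPM in Vegt MO. Leaving out any 1 of the libraries compared left 0 calls in Vegt MO and in Double MO. Over all alternatives run, the log2 fold change of Xetrov90018018m.g in Vegt MO ranged from -4.01 to -3.55. In Double MO the ranges were -4.08 to -3.52 for Xetrov90026354m.g, -3.10 to -2.50 for Xetrov90010375m.g and 2.65 to 3.17 for Xetrov90009021m.g. With the block, 174 features were higher and 254 lower in Vegt MO, 118 and 154 in Otx1 MO and 476 and 660 in Double MO. Without uninjected replicate 2, an alternative chosen after seeing the data, the blocked totals were 502, 112 and 465. Double MO against Vegt MO and against Otx1 MO gave 0 calls each without the block (988 and 374 features at an unadjusted p under 0.05; DESeq2 called 102 and 43 and limma 1 and 1), and 336 higher and 332 lower, and 19 higher and 70 lower, with it. The interaction of both morpholinos gave 0 calls with edgeR in either fit, with 157 features at an unadjusted p under 0.05 without the block, and 0 with DESeq2 and limma.

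Call lists of both explant experiments were compared feature by feature. Without the block 0 features fell in Double MO and rose in caps with 100 ng of each RNA (lists of 9 and 8). With the block 38 did, against 8.34 for independent lists (Fisher's exact test, one-sided, adjusted p = 1.18e-14), and 14 features rose in Double MO and fell in those caps against 4.72 (adjusted p = 0.00051). Features that rose in both numbered 18 against 6.36 (adjusted p = 0.00016), and 3 fell in both against 6.18. Between Vegt MO and caps with 500 ng of vegt RNA, 0 features fell and rose, respectively, without the block (lists of 2 and 111), and the list of features that rose in Vegt MO was empty. The blocked lists shared 52, against 6.63 (Fisher's exact test, adjusted p = 7.62e-31), and 30 that rose and fell, against 2.13 (adjusted p = 2.29e-25). Features that rose in both numbered 18 against 4.89 (adjusted p = 6.5e-06), so that the excess was not limited to features that moved in opposite directions. Between Otx1 MO and the addition of 100 ng of otx1 RNA the lists without the block were empty; with it 5 features fell and rose, respectively, against 0.38 (adjusted p = 8.87e-05), 2 rose and fell against 0.32 (adjusted p = 0.064), 1 rose in both and 0 fell in both.

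Without the block Vegt MO and Otx1 MO shared 0 lower features, since the Otx1 MO list was empty. With it they shared 24 (lists of 254 and 154), against 2.40 for independent lists. In 20 simulations of unchanged groups the blocked overlap had a median of 0 and a maximum of 2; such groups give few calls to share, so this value does not bear on lists of that length. Both comparisons use the same 2 uninjected libraries. Across features their fold changes correlated with r = 0.32 without the block and 0.30 with it, below the 0.51 of simulated unchanged groups in both fits. That simulated value comes from the shared controls alone, and changes particular to a single morpholino lower it. The lower correlation thus does not show that the responses were less alike than chance. The covariance was 0.16 against 0.0975 simulated without the block, a difference of 0.065, and 0.15 against 0.0945 with it, a difference of 0.055. Part of the overlap may come from the shared controls, which could not be split without leaving 1 library on each side.

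The binding data asked which regions the 3 factors share. The series design text names 1 library of the other series as used for all 3 factor lists, so these lists were not made from fully separate libraries. The lists held 21711 Vegt, 5151 Otx1 and 39218 Foxh1 peaks, with median lengths of 342, 324 and 308 bp. Otx1 peaks lay mostly within the other lists: 77.1% overlapped a Foxh1 peak and 63.7% a Vegt peak, against means of 2.13% and 1.5% in 1000 shifts (one-sided permutation p = 0.001 each). Of Vegt peaks 27.1% overlapped Foxh1, against 2.12% (permutation p = 0.001). Where peaks overlapped, median distances between summits were 23 bp between Otx1 and Vegt, 29 bp between Otx1 and Foxh1 and 29 bp between Vegt and Foxh1. Only overlapping peaks were measured, which by itself keeps distances short, and no value from shifts was taken. The Vegt peak with the highest fold enrichment in the authors' list, 40.4, lay on chromosome 2 at 101205335 to 101206493 and overlapped Otx1 and Foxh1 peaks, and the highest Otx1 peak, at 11.9, lay in the same place at 101205505 to 101206262. The genome build of these coordinates is not given in the sources used here.

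The last comparison asked whether regions bound at these early stages carry H3K4me1 at stage 10.5. Pooled over which factors were bound, the share grew with their number, though not for every combination of factors. Of 46756 merged regions with 1 factor, 6.31% (95% Wilson interval 6.1% to 6.54%) overlapped one of the 15925 H3K4me1 peaks, of 6149 with 2 factors 15.8% (14.9% to 16.8%) and of 2315 with all 3 factors 33.5% (31.6% to 35.5%), against means of 1.18%, 1.45% and 1.48% in shifts of the mark (one-sided permutation p = 0.001 each). The level depended on the overlap asked for: with at least 0.5 of the region covered by the mark the shares were 3.92%, 9.46% and 17.5%, in the same order of factors. Among regions of 1 factor, Vegt alone had 3.40%, Foxh1 alone 7.59% and the 205 regions with Otx1 alone 19.5%. In shifts of the mark the means of these classes were 1.19%, 1.15% and 5.18%. Relative to these means, Vegt alone was at 2.85 times, Foxh1 alone at 6.58 times and Otx1 alone at 3.77 times. The order of Foxh1 alone and Otx1 alone thus depended on whether the shifts were taken into account. Among regions of 2 factors, Vegt with Otx1 but no Foxh1 peak had 9.32%, Vegt with Foxh1 15.2% and Otx1 with Foxh1 21.1%. Their shift means were 2.16%, 1.29% and 1.37%.

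**Figure D4:**
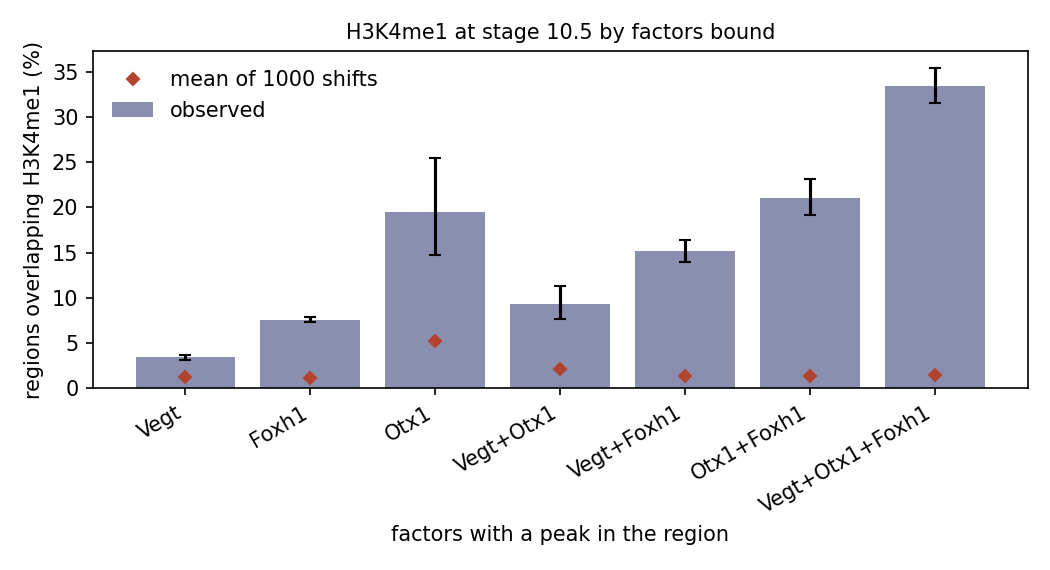
Percent of merged bound regions that overlap an H3K4me1 peak, by the factors with a peak in the region; error bars are 95% Wilson intervals and diamonds the mean of 1000 circular shifts of the mark. Regions with all 3 factors had 33.5% and regions with Vegt alone 3.40%.

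Bound regions stitched at the preset distance formed 27472 clusters, of which 55.9% held a single region. The 222 clusters with at least 10 regions had a median length of 43057 bp, and 148 of them (66.7%) held at least 1 region bound by all 3 factors. They contained 12.9% of the regions bound by all 3 factors and 5.1% of all bound regions. These shares depended on the distance: within 5000 bp 31 such clusters held 1.81% and 0.704%, and within 25000 bp 866 held 36.7% and 22%. Of the clusters placed on chromosomes, 2 held 6 regions with all 3 factors, the most there. On chromosome 3, a cluster at 86579504 to 86648421 held 19 regions, 6 with all 3 factors, and on chromosome 7, one at 91343029 to 91399992 held 16 regions, 6 with all 3 factors and 11 with H3K4me1.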

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

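None of the identifiers picked by the preset rule changed the sign of its fold change under the alternatives run. Nor did the median of any set that camera called with both correlations. For the identifiers, printed or not, this was nearly settled in advance, because the rule took great changes with no overlap between replicate values. Medians of other sets were not judged for a change of sign. RLE scaling kept each count of calls within 1.5 times and its share of higher calls within 10 percentage points. The replicate block raised the counts in every comparison except the interaction, which stayed at 0: 180 calls for vegetal against animal blastomeres; 7, 71, 219 and 690 at 50 to 500 ng of vegt RNA and 827 in its trend; 7, 19, 92 and 123 for otx1 amounts and trend; 428, 272 and 1136 for Vegt, Otx1 and Double MO; 668 and 89 for Double MO against Vegt MO and Otx1 MO. Chosen after seeing the data, the block gave 38 and 24 shared features in the overlaps of Double MO with caps and of Vegt MO with Otx1 MO, 247 calls without 8-cell libraries of number 3, and 502, 112 and 465 without uninjected mass replicate 2. With DESeq2, counts were 160; 21, 43, 124, 380 and 434; 1, 15, 40 and 45; 161, 59 and 263; 102 and 43, in the same order, and the overlaps 10 and 3; the morpholino counts were 84 higher and 77 lower in Vegt MO, 24 and 35 in Otx1 MO and 79 and 184 in Double MO. With limma on TPM, 2, 41 and 201 features were called at 100, 200 and 500 ng of vegt RNA, 6 and 8 at 100 ng of otx1 RNA and in its trend, 18 in Double MO, and 1 each in Double MO against Vegt MO and Otx1 MO. Without the filter, 5 were called at 100 ng of vegt RNA, 48, 9 and 50 in Vegt, Otx1 and Double MO (28, 2 and 14 of them higher), and 14 and 6 in Double MO against each. With only the libraries compared, 37 were called for the blastomeres and 0 in Vegt MO and Double MO, where fewer libraries estimate the spread. Leaving out 1 library gave 32 to 66 calls for the blastomeres, 0 to 2, 0 to 17 and 44 to 82 at 100, 200 and 500 ng, 74 to 143 in the vegt trend, and 0 to 0 in Vegt MO and Double MO; a group left with 1 library is assumed to vary like the others. For peaks, the top scores of each list gave 48.7% of Otx1 peaks at Vegt and 18.1% of Vegt peaks at Foxh1. H3K4me1 shares for 1, 2 and 3 factors were 8.50%, 23.1% and 39.2% in the top lists, and 3.92%, 9.46% and 17.5% when at least 0.5 of the region had to be covered, in the same order of factors. Stitching within 25000 bp gave 17685 clusters, 866 of them with at least 10 regions. The cause of these shifts was not tested, except where fewer libraries, features or peaks follow from the setting. Motif and distance alternatives were not run. At these depths and group sizes, the simulation recovered 0% of 2-fold changes in Double MO without the block and 64% with it. These shares hold only for features above its minimum mean count.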

Other observations

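The tests of the injected amounts, of the share of counts in abundant features, of the animal and other maternal features in the uninjected masses and of the sample splits were chosen after the results were seen. Features with little maternal RNA also responded in the masses. With the replicate block, features under 0.1 TPM at the 8-cell stage made up 20.5% of those lower in Vegt MO, 25.3% in Otx1 MO and 19.4% in Double MO, against 9.97%, 10.2% and 9.91% of features not called (Fisher's exact test, two-sided, adjusted p = 3.99e-06, 6.67e-07 and 1.11e-11). Among features higher in these masses the share was 21.8%, 3.39% and 8.82% (adjusted p = 2.03e-05, 0.028 and 0.66). The lncRNA models made up 20.5% of the 254 features lower in Vegt MO (against 14.3%; adjusted p = 0.020), 8.44% of the 154 lower in Otx1 MO (against 14.4%; adjusted p = 0.069) and 9.85% of the 660 lower in Double MO (against 14.8%; adjusted p = 0.00087). They made up 4.02% of those higher in Vegt MO (adjusted p = 5.56e-05), 5.08% in Otx1 MO (adjusted p = 0.0058) and 3.78% of those higher in Double MO (adjusted p = 1.59e-13). The differences between the morpholinos in these shares were not tested. Features were not matched for level in these tests either, so an effect of level was not separated from one of feature class.

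A hypothesis is that the features that followed the injected amounts may count reads of the injected RNA itself, which would rise in proportion to dose. The slope of log2 TPM above the level without that RNA on log2 amount was 0.939 (SE 0.072) over 8 libraries for Xetrov90002928m.g with vegt RNA and 1.09 (SE 0.076) over 6 libraries for Xetrov90013341m.g with otx1 RNA, both near 1. The test does not single these features out: over the 143 features of the vegt trend with a slope, the quartiles were 0.666 and 1.2, and 59 lay in the range taken as near 1, as did 21 of 46 in the otx1 trend. An induced gene stays open.

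The split of caps and masses by replicate number was set against technical explanations. After thinning all libraries to the smallest total, the first component still parted the numbers and held 50.78% or more of the variance in both tables, which argues against library depth. The values also argue against a few features taking most of the counts, since a library's 50 most abundant features held at most 17.6%. That share of counts did differ by number in the caps, at 10.1% to 11.6% in number 1 and 13.4% to 17.6% in number 2. Without the 50 most abundant of each table the component held 51.18% or more and still parted the numbers. This removal decides nothing by itself, because so few of the tested features could hardly move the component. Clutch, day and library batch cannot be told apart here, because the labels give none for these explants; no biological explanation was tested.

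Uninjected mass replicate 2, set against the mean of the morpholino masses of its number, was lower in 60 vegetal maternal features than replicate 1 set against its own, by a median of -0.66 (95% bootstrap interval -0.82 to -0.47); these intervals resample features, which are correlated, and not the single libraries compared. It did not stand alone, since Vegt MO replicate 2 differed from it by a median of -0.056, and Otx1 MO and Double MO replicate 2 by 0.63 and 0.77. Scaling holds the median of most features near 0, so sets were compared with each other: the vegetal features lay below 8009 other maternal features by -0.673 (-0.808 to -0.48), which argues against a loss alike in all maternal RNA and leaves open a loss of RNA that is not made anew. A larger share of animal tissue in the explant would raise animal features; the median of 50 such features was 0.117 (-0.0645 to 0.253), which leaves it open. An effect of the Otx1 morpholino on these features within number 2 and variation between single libraries also stay open.

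H3K4me1 was most frequent where all 3 factors had peaks, and Foxh1 peaks there were stronger, with a median fold enrichment of 26.6 against 13.5 for Foxh1 alone. Within 10 strata of the Foxh1 fold enrichment the Mantel-Haenszel odds ratio was 5.02 (95% interval 4.47 to 5.63), against 6.03 without that division, so Foxh1 peak strength was not the whole cause. At the Foxh1 summit base alone it was 3.58 (3.1 to 4.13), so region length was not the whole cause either. Chromatin that is accessible to any factor may give the same pattern and was not tested. Regions are not independent, and the intervals cover counting error only.

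For the 8-cell comparison, the real split of the 6 blastomere libraries gave 63 calls and the highest of the other splits 0; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Among the 4 splits that part all 3 pairs, the blocked fit gave 180 calls for the real one and at most 0 for the others; the other 6 splits part 1 pair each.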
